A study of Homo sapiens with 6 samples.

How the data were processed

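Polyadenylated mRNA and ribosome-nascent-chain-bound polyadenylated mRNA (RNC-mRNA) of 3 hepatocellular carcinoma lines were sequenced, per the labels. Libraries were made with an NEBNext mRNA preparation kit, per the labels' protocols, and each was a pool of equal amounts from 3 cultures, per the design text. Hep3B was grown in MEM with 15% fetal bovine serum and HCCLM3 and MHCC97H in DMEM with 10%, per the labels. The aligner, the counting program and its handling of strand, multiply mapped reads and overlapping genes are not given in the sources used here. The submitters' processing notes name edgeR and the genome build hg19, without saying where edgeR was used.

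For each library the authors deposited a table with a read count and an RPKM value per gene. The deposited counts were whole numbers of at least 1, and a gene without reads had no line. The deposited RPKM values were these counts scaled by gene-model length in kilobases and by a library total set by the authors. That total and the gene-model lengths were recovered from the counts and RPKM, and recovered lengths lay within 8.9e-09 of whole numbers. The authors' totals were 132786306, 157181586, 129948939, 147499070, 142785469 and 150607183 reads for Hep3B mRNA, Hep3B RNC-mRNA, HCCLM3 mRNA, HCCLM3 RNC-mRNA, MHCC97H mRNA and MHCC97H RNC-mRNA. The tables name a line and a letter, A or C. C was read as RNC-mRNA, because among the sample titles a C occurs in the word RNC alone, and A as mRNA by elimination. No label states the letters outright, and all ratios of the fractions depend on this reading.

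A gene at 1 RPKM with a 3 kb model had 390 to 472 reads in these libraries. From counting alone, the 95% half-width of a log2 ratio was 0.13 with 1000 reads in each library and 0.40 with 100. Because no replicates exist for a line and fraction, these widths leave out all variation between cultures and preparations. The 10 most abundant genes took 8.45, 11.0, 6.73, 5.00, 6.94 and 5.29% of the reads, in the order of libraries given for the totals.

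The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Line differences were described by a size rule: a ratio of (RPKM + 0.1) of at least 4, with at least 1 RPKM in the higher library, pairwise and for a line against both others. The ratio of RNC-mRNA to mRNA in a line was log2 of (RPKM + 0.1) in RNC-mRNA over that in mRNA, for genes with at least 1 RPKM in both fractions, and ratios of at least 2 or at most 0.5 were counted. Such fold changes understate those of low genes. No p-value was computed for either, since each compares single libraries. The ratio over the 3 lines was tested on the deposited counts with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, cell line as a block) in genes with a mean RPKM of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. The line is a natural pairing, since both fractions come from the same line. With each line kept separate, a difference between lines in the ratio has no residual degrees of freedom in this design and was not tested. Hep3B against HCCLM3 and MHCC97H taken as a group was not tested either.

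For each of 29 gene lists written in advance, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is no test. The lists covered hepatocyte secreted proteins, transcription factors and metabolism, oncofetal, epithelial, mesenchymal, invasion, proliferation, p53 target, interferon, inflammatory, glycolysis, cholesterol, ribosomal protein, translation factor, aminoacyl-tRNA synthetase, stress response, endoplasmic reticulum, oxidative phosphorylation, proteasome, spliceosome, iron, zinc finger and histone genes, noncoding RNA, and markers of stellate, endothelial, leukocyte and erythroid cells. Over the 3 lines, 24 of the lists were tested with camera of limma 3.58.1, with its preset and with an estimated correlation. After the values were seen, 3 lists were added (immediate early genes, NRF2 targets, hypoxia-inducible genes).

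Named genes were a panel of 13, the 5 genes with the widest gap in each line class met in both fractions, up to 4 members of each list with the largest ratio, and the 10 highest and 10 lowest mean RNC-mRNA to mRNA ratios among genes with at least 5 RPKM in every library and the same sign in each line. Genes of the Y chromosome were left out. Of the 19089 gene names 16677 matched a current symbol of the RefSeq annotation on GRCh38.p14 and 18159 a current or older one. As that assembly differs from hg19, it served only for gene types and for which genes are neighbours.

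Alternatives were pseudocounts of 1 and 0.01 RPKM, no expression filter and one at 5 RPKM, rescaling to the median ratio or the upper quartile, genes at 1 RPKM in all 6 libraries, no line block, each line left out in turn, and DESeq2 1.42.0. Added after the data were seen were the authors' totals without further scaling and an offset for gene-model length, a running median over 200 genes on either side in each line. The edgeR step was tested on simulated counts for this comparison, in 4 runs of 200 changed genes among 11905. With trended dispersions drawn into the counts it recovered 13, 69.5, 99 and 100% of genes changed 1.5, 2, 3 and 4-fold, with 3.1% unchanged genes among those called. With gene-wise dispersions it recovered 5, 52.5, 94 and 99%, with 10.05% unchanged genes among those called, above the nominal 5%. With no changed genes it called 0. The simulated fraction effect was the same in all lines, and libraries were drawn independently around line means. Relatedness of the lines and ratios particular to 1 line were left out, so these shares need not hold for the data. The list percentile was tested on simulated ratios for the 10825 genes measured in Hep3B, with 400 lists of 30 genes. Only the expression levels came from Hep3B, and noise was drawn independently for each gene. Of unshifted lists 3.25% lay outside the central 95%, and 95.0% of lists shifted by 0.5 lay above it. No length trend or correlation among list members was simulated, so these shares need not hold for the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 were used.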

Results

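The data were 6 RNA sequencing libraries from 3 human hepatocellular carcinoma cell lines, Hep3B, HCCLM3 and MHCC97H. HCCLM3 and MHCC97H are related lines known for high metastatic capacity and share a parental line, so they are not independent of each other. From each line, polyadenylated mRNA of the whole cell (mRNA) and polyadenylated mRNA bound to ribosomes that carry a nascent chain (RNC-mRNA, the mRNA in translation) were sequenced. Each library was made from a pool of 3 cultures, so each line and fraction had 1 library and no replicates. The gene tables held 119086844 reads for Hep3B mRNA, 147788269 for Hep3B RNC-mRNA, 119888529 for HCCLM3 mRNA, 141095635 for HCCLM3 RNC-mRNA, 132684373 for MHCC97H mRNA and 144209109 for MHCC97H RNC-mRNA. The column letters A and C were read as mRNA and RNC-mRNA, and no label states them outright. If they were exchanged, every RNC-mRNA to mRNA ratio would change sign.

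The most abundant transcript differed between the libraries. IGF2, a fetal growth factor, took 2.38% of the reads in Hep3B mRNA and 2.36% in Hep3B RNC-mRNA. FN1, which encodes fibronectin, took 1.23% in HCCLM3 mRNA and 1.67% in MHCC97H mRNA, whereas ACTB, which encodes beta-actin, led their RNC-mRNA libraries with 0.721% and 0.756%. Over the 6 libraries 19089 genes had at least 1 read in a library, and 16275 of them had reads in all 6. An RPKM of at least 1 was reached by 11742 genes in Hep3B mRNA, 10942 in Hep3B RNC-mRNA, 11467 in HCCLM3 mRNA, 11152 in HCCLM3 RNC-mRNA, 11489 in MHCC97H mRNA and 11186 in MHCC97H RNC-mRNA. Of all genes, 17878 matched a gene annotated as protein-coding and 175 a long noncoding RNA. Most genes were seen in both fractions of a line (17243 in Hep3B, 17210 in HCCLM3 and 17307 in MHCC97H). Genes seen in mRNA alone numbered 773, 620 and 603, with a median of 2, 1 and 1 reads, and those seen in RNC-mRNA alone numbered 284, 397 and 360, with a median of 1 read in each line. At 1 or 2 reads absence from a fraction is within counting error, while 2 of the genes seen in Hep3B mRNA alone reached 1 RPKM. Intervals and floors cover counting error only.

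The first comparison asked which genes set the lines apart in mRNA and in RNC-mRNA. Hep3B carried a hepatocyte and fetal liver programme that was low in both other lines. ALB, which encodes serum albumin, stood at 4164 RPKM in Hep3B mRNA, 1.93 in HCCLM3 and 12 in MHCC97H. IGF2 stood at 3826, 1.5 and 1.3 RPKM, and AFP, the alpha-fetoprotein gene of fetal liver and liver tumours, at 109, 2.16 and 1.88 RPKM. The reverse held for S100A4, a calcium-binding protein tied to cell motility, at 0.858 RPKM in Hep3B mRNA against 2502 and 1912, and for SPP1, which encodes the secreted matrix protein osteopontin, at 0.407 against 365 and 245. In RNC-mRNA the same genes were as far apart, with ALB at 4908, 1.03 and 6.90 RPKM and S100A4 at 1.54, 3006 and 2819.

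By the size rule, a ratio of at least 4 with at least 1 RPKM in the higher library, 1083 genes were higher and 1263 lower in HCCLM3 than in Hep3B mRNA, of 12737. For MHCC97H against Hep3B the counts were 1039 higher and 1201 lower of 12728. In RNC-mRNA they were 1350 higher and 1189 lower of 12212 for HCCLM3, and 1348 higher and 1167 lower of 12222 for MHCC97H. The median log2 ratio over genes at 1 RPKM in all 6 libraries was 0.24 for HCCLM3 over Hep3B and 0.25 for MHCC97H over Hep3B in RNC-mRNA as deposited. Rescaling the libraries to the median ratio brought it to -0.01 for both, and in mRNA it was near 0 in either case.

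**Figure D1:**
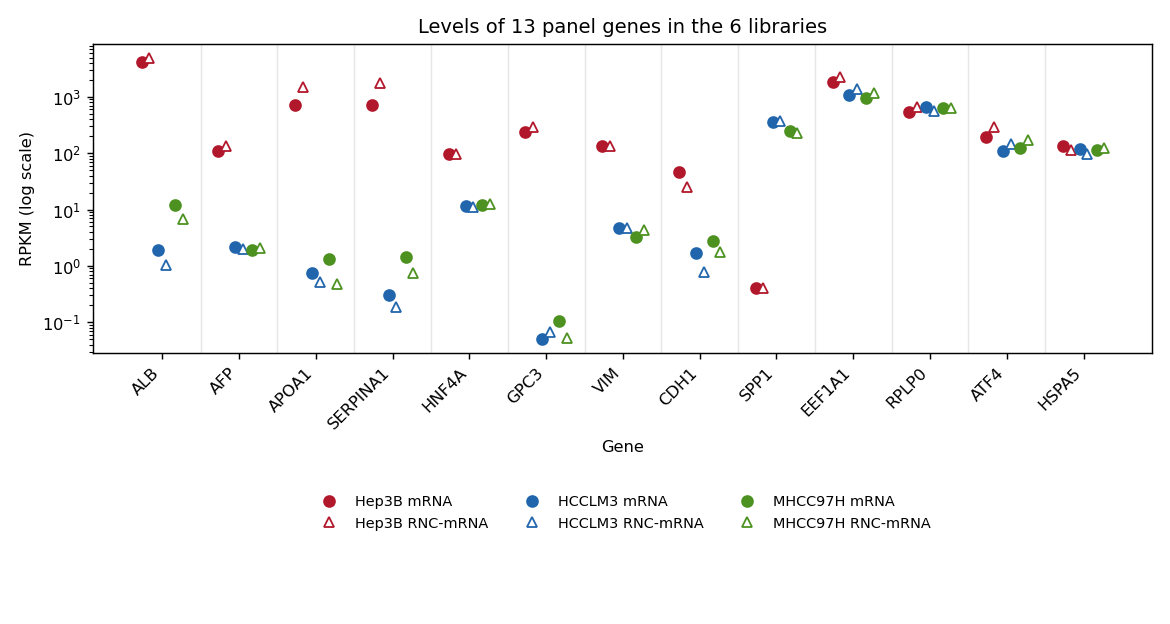
Levels of 13 genes chosen in advance, in RPKM on a log scale, with filled circles for mRNA and open triangles for RNC-mRNA of Hep3B (red), HCCLM3 (blue) and MHCC97H (green), 1 library per symbol. ALB is at 4164 RPKM in Hep3B mRNA against 1.93 in HCCLM3 and 12 in MHCC97H, SPP1 goes the other way, and RPLP0 stays between 544 and 673 in all 6 libraries.

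Genes for plasma proteins that hepatocytes secrete formed the group with the widest gap. Of 36 measured members, 31 were lower by the size rule in HCCLM3 than in Hep3B mRNA and 2 higher, with a median log2 ratio of -6.07, below all of 10000 random gene lists of matched expression. In MHCC97H 30 of 35 were lower and 1 higher (median -5.76), and in RNC-mRNA 33 of 37 and 33 of 36 were lower (medians -6.82 and -6.78). APOA2, an apolipoprotein of high-density lipoprotein, stood at 4566 RPKM in Hep3B mRNA and at 1.08 and 2.36 in HCCLM3 and MHCC97H. GC, which encodes the vitamin D binding protein, stood at 265 RPKM against 0.0351 and 0.103, and APOB, the structural protein of low-density lipoprotein, at 367 against 0.0932 and 0.367. APOA1 was at 712, 0.740 and 1.32 RPKM and SERPINA1, which encodes alpha-1 antitrypsin, at 722, 0.309 and 1.46. AL590714.1 followed APOA2 in every library (4591 RPKM in Hep3B mRNA) and is reported as uncertain, since the handling of overlapping gene models is not given in the sources used here.

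Hepatocyte transcription factors were lower as well, 11 of 19 in HCCLM3 mRNA with 1 higher, and 10 of 18 in MHCC97H mRNA with 0 higher (medians -2.80 and -2.43, both below all random lists; in RNC-mRNA -2.75 and -2.72). NR0B2, a bile acid responsive nuclear receptor, was at 62.0 RPKM in Hep3B mRNA against 0.346 and 0.315. HNF4A, the nuclear receptor central to hepatocyte identity, was at 94.9 RPKM in Hep3B, 11.3 in HCCLM3 and 12 in MHCC97H. Oncofetal and progenitor genes were lower in 13 of 18 and 12 of 18, and higher in 2 and 0 (medians -3.64 and -4.38 in mRNA, -2.80 and -4.73 in RNC-mRNA). They included GPC3, a cell-surface proteoglycan used as a liver tumour marker (243 RPKM against 0.0509 and 0.104), DLK1 (215 against 0.0407 and 0.202) and EPCAM (143 against 0.290 and 0.203). Hepatocyte metabolism genes were mixed, with 10 of 24 lower and 3 higher in HCCLM3 mRNA (median -0.73) and 10 of 25 lower and 3 higher in MHCC97H (median -0.61). In RNC-mRNA their medians were -1.61 and -1.12. ASS1 of the urea cycle was at 99.9 RPKM in Hep3B mRNA against 0.484 and 2.05.

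Mesenchymal genes as a list were higher in HCCLM3 and MHCC97H, in 11 of 19 and 14 of 21 members in mRNA with 2 lower in each (medians 3.41 and 3.40, above all random lists; 3.55 and 3.47 in RNC-mRNA). Besides S100A4, COL6A1 of collagen VI was at 0.142 RPKM in Hep3B mRNA against 207 and 260, ANXA1 at 0.116 against 135 and 116, and CAV1, the caveolae protein, at 3.38 against 1266 and 1066. VIM, which encodes the intermediate filament vimentin, went against the list at 135 RPKM in Hep3B, 4.65 in HCCLM3 and 3.26 in MHCC97H. Invasion and matrix genes were higher in 18 of 36 in each line and lower in 5 and 4 (medians 2.09 and 1.90 in mRNA, 1.93 and 2.19 in RNC-mRNA, all above all random lists). MMP7, a secreted protease, was at 0.0911 RPKM against 119 and 87.4, and CD44, the hyaluronan receptor, at 0.0181 against 71.1 and 72.3. Epithelial junction and keratin genes were lower in 11 of 26 and 10 of 27 and higher in 4 of each (medians -1.70 and -1.24 in mRNA, -1.45 and -1.04 in RNC-mRNA). CDH1, which encodes E-cadherin, was at 46.0 RPKM in Hep3B mRNA against 1.68 and 2.74, and CLDN1 of the tight junction at 105 against 0.188 and 0.517. CLDN4, also of the tight junction, was at 0.581 RPKM against 61.7 and 64.5.

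Interferon and antigen presentation genes were higher in 8 of 28 and 10 of 29 and lower in 2 of each in mRNA (medians 0.71 and 0.82, percentiles 99.6 and 99.9 of the random lists; 0.39 and 0.87 in RNC-mRNA, percentiles 67.1 and 99.0). OAS1, an antiviral nucleotide synthetase, was at 0.337 RPKM in Hep3B mRNA against 46.0 and 33.3. Glycolysis and hypoxia genes were higher in 11 of 27 and 9 of 27 and lower in 3 and 2 (medians 1.61 and 1.42 in mRNA, 1.01 and 0.76 in RNC-mRNA). The lines used different hexokinases, the first enzymes of glycolysis: HK2 was at 58.2 RPKM in Hep3B mRNA against 0.0587 and 0.0764, and HK1 at 0.0792 against 61.9 and 54.6. Integrated stress response genes had medians of -0.86 and -0.62 in mRNA and -0.96 and -0.73 in RNC-mRNA. Among them MTHFD2, a mitochondrial folate enzyme, was at 29.5 RPKM against 0.219 and 0.233. Cholesterol synthesis genes had medians of -0.46 and -0.25 in mRNA and -0.97 and -0.94 in RNC-mRNA, with TM7SF2, a sterol reductase, at 63.2 RPKM against 3.69 and 3.15. Inflammatory and acute phase genes had mRNA medians of -0.07 and -0.03, with 4 higher and 4 lower of 19 in both lines (0.12 and 0.57 with no expression filter), and RNC-mRNA medians of 1.41 and 2.35. SOCS3, an inhibitor of cytokine signalling, was at 0.0993 RPKM against 7.42 and 11.4. Replication-dependent histones had mRNA medians of 1.57 and 1.22 (5 of 13 and 3 of 12 higher), which in polyadenylated RNA covers a part of their transcripts.

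Housekeeping groups differed little between the lines in mRNA. None of the 35 proliferation genes, the 79 ribosomal proteins, the 75 nuclear encoded genes of oxidative phosphorylation or the 31 proteasome genes reached a ratio of 4 in mRNA, and their medians for HCCLM3 over Hep3B were 0.05, 0.02, 0.31 and 0.43. For MHCC97H over Hep3B they were 0.09, 0.01, 0.26 and 0.35, of which the ribosomal protein median fell on the other side of 0 when the libraries were rescaled to the median ratio. In RNC-mRNA, where the median of all genes was shifted by 0.24 and 0.25, the medians in HCCLM3 and MHCC97H over Hep3B were 0.53 and 0.64 for proliferation, -0.09 and -0.15 for ribosomal proteins, 0.50 and 0.60 for the proteasome and 0.49 and 0.52 for the spliceosome. Oxidative phosphorylation genes had 0.19 and 0.14, below 0 (-0.05 and -0.12) after rescaling to the median ratio and in MHCC97H (-0.04) also to the upper quartile, with 1 member higher and 1 lower by the size rule in HCCLM3 and 1 higher and 2 lower in MHCC97H. EEF1A1, a translation elongation factor, was at 1807 RPKM in Hep3B mRNA, 1061 in HCCLM3 and 970 in MHCC97H. ATF4, a stress-induced transcription factor, was at 197, 112 and 122 RPKM, and HSPA5, a chaperone of the endoplasmic reticulum, at 133, 117 and 115. Translation factors with a TOP motif had mRNA medians of -0.34 and -0.22, aminoacyl-tRNA synthetases -0.35 and -0.25, endoplasmic reticulum folding genes -0.001 and 0.03, spliceosome genes -0.02 and 0.02, iron response element genes -0.17 and 0.07, C2H2 zinc finger genes -0.22 and -0.25, and p53 targets -0.30 and -0.22. The HCCLM3 medians of endoplasmic reticulum folding and spliceosome genes were above 0 after rescaling to the upper quartile. Markers of other cell types were mostly at low levels. Of 12 stellate cell and fibroblast markers 4 reached 1 RPKM in a library, PDGFRB and PDGFRA being higher in Hep3B (medians -1.69 for HCCLM3, which became 0.005 with no filter, and -4.71 for MHCC97H over Hep3B mRNA). Of 12 endothelial markers 4 did, ESAM being higher in HCCLM3 and MHCC97H (medians 1.86 and 3.70, with 1 of 3 and 3 of 4 higher and 1 and 0 lower). Of 14 leukocyte markers 4 did (medians -0.74, which became 0.70 with a filter at 5 RPKM, and -0.61), with LYZ at 78.3 RPKM in Hep3B mRNA against 0.860 and 0.787. Of 12 erythroid and other lineage markers 2 did, too few for a median, and of the 34 genes in the noncoding RNA list 0 matched a gene in the tables used here. The Hep3B cells were grown in another medium with 15% rather than 10% serum, so line and medium cannot be told apart in these comparisons, which had no replicate check.

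HCCLM3 and MHCC97H, compared with each other, were nearly alike, with 26 genes higher and 39 lower in HCCLM3 mRNA of 11715, and 37 higher and 42 lower in RNC-mRNA of 11383. As a list, hepatocyte secreted proteins were higher in MHCC97H. FGB and FGG, which encode fibrinogen chains, were at 0.803 and 0.205 RPKM in HCCLM3 mRNA and 16.5 and 2.02 in MHCC97H, and the list median was -0.59 in mRNA and -0.58 in RNC-mRNA, below all random lists, with 3 of 24 and 3 of 18 members lower. CLDN2, a tight junction protein, was at 2.45 RPKM in HCCLM3 mRNA and 19.9 in MHCC97H. Invasion genes had medians of -0.03 in mRNA and -0.29 in RNC-mRNA, and mesenchymal genes 0.12 and -0.22, with 0 members at a ratio of 4 in either list.

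Taking both fractions, 897 genes were at least 4-fold higher in Hep3B than in each other line and 834 at least 4-fold lower. Those with the widest gaps were APOA2, IGF2, AL590714.1, GC and GPC3 on the high side. On the low side stood S100A4, S100A3 (0.0440 RPKM in Hep3B mRNA against 290 and 279), AKR1B1, an aldose reductase (0.538 against 977 and 692), KRT20, an intestinal keratin (0.0260 against 213 and 274), and CES1, a liver carboxylesterase (0.114 against 385 and 394). HCCLM3 stood above both other lines in 11 genes (6 with a pseudocount of 1 or a filter at 5 RPKM) and below both in 7 (1 to 16 over the alternatives). The high ones were led by FGF13 (3.36 RPKM in HCCLM3 mRNA, 0.204 in MHCC97H and 0.0113 in Hep3B), PPP2R2B (1.56, 0.147 and 0.0585) and the cancer-testis genes SSX1, SSX6 and SSX9. SSX1 was at 85.0 RPKM in HCCLM3 and 7.46 in MHCC97H, and the members of this family are near-identical copies, so reads assigned to each are uncertain. The low ones were led by GPR126 (0.0657 RPKM against 1.57 in MHCC97H), PNMA6C (0.143 against 2.26), ALB, ANPEP, an aminopeptidase of the bile canaliculus (5.48 against 32.9), and FGG. MHCC97H stood above both other lines in 18 genes (5 to 24 over the alternatives), led by ITM2A (51.0 RPKM in MHCC97H mRNA and 0.412 in HCCLM3), WNT4 (1.98 and 0.0846), CSAG1 (5.54 and 0.0594), GAGE12J (7.26 and 0.512) and GAGE12I (3.60 and 0.252), the GAGE genes again being near-identical copies and uncertain. It stood below both in 7 (2 to 10 over the alternatives), led by the imprinted neighbours SGCE (0.449 RPKM against 8.09 in HCCLM3 and 15.4 in Hep3B) and PEG10 (0.529 against 7.20 and 82.4), with LGR5, ACSS3 and GPR161.

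The line differences were close to the same in the 2 fractions. Across genes, which are not independent replicates, the log2 ratios in mRNA and in RNC-mRNA correlated with Pearson's r = 0.940 for HCCLM3 over Hep3B (12900 genes), 0.943 for MHCC97H over Hep3B (12888 genes) and 0.883 for HCCLM3 over MHCC97H (11918 genes), with Spearman's rho of 0.859, 0.856 and 0.793. In these pairs 2079, 2029 and 64 genes met the size rule the same way in both fractions, and 0 met it in opposite ways. An opposite call needs a ratio of 4 each way. Few could arise, as the RNC-mRNA to mRNA log2 ratios had SDs of 0.63, 0.46 and 0.47 in Hep3B, HCCLM3 and MHCC97H. The first 2 correlations share the Hep3B libraries.

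The next comparison asked which mRNAs were over- or under-represented among ribosome-bound mRNA in each line. The ratio is relative to the other genes of the same libraries and is no absolute share of bound molecules. Transcripts of secreted liver proteins stood high in Hep3B and low in the other lines. AHSG, which encodes fetuin-A, had a log2 ratio of 0.98 in Hep3B, -0.24 in HCCLM3 and -0.44 in MHCC97H, ALB had 0.24, -0.85 and -0.79, and TF, which encodes transferrin, 0.10, -1.08 and -0.94. APOA1 and SERPINA1 had 1.07 and 1.27 in Hep3B and were under 1 RPKM in a fraction of each other line. As a list, hepatocyte secreted proteins had a median of 0.91 in Hep3B (34 genes, percentile 100 of random lists), -0.44 in HCCLM3 (14 genes, percentile 0) and -0.36 in MHCC97H (17 genes, percentile 0.05). APOB, whose transcript is among the longest of the list, had -2.01 in Hep3B. Inflammatory genes had medians of -0.34, 0.51 and 0.64 (9, 15 and 16 genes, percentiles 7.58, 99.8 and 100). The chemokine CXCL5 had log2 ratios of -1.90, 0.39 and 0.63, and CCL20, another chemokine, 0.02, 1.37 and 1.22.

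A ratio of at least 2 was reached by 205 genes of 10825 in Hep3B, 92 of 10930 in HCCLM3 and 51 of 10987 in MHCC97H, and a ratio of at most 0.5 by 837, 270 and 295. The library medians were -0.03, 0.17 and 0.16, and with each ratio taken against its library median the counts were 232 and 781 in Hep3B, 29 and 404 in HCCLM3, and 22 and 439 in MHCC97H. Across 9662 genes the ratios of HCCLM3 and MHCC97H correlated at r = 0.946, and those of Hep3B with them at 0.352 and 0.387 (Spearman's rho 0.931, 0.244 and 0.276).

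Metabolic groups shared the high ratio in Hep3B. Cholesterol synthesis genes had medians of 0.59 in Hep3B, -0.14 in HCCLM3 and -0.01 in MHCC97H, with INSIG1, a sterol sensor, at 1.17, 0.32 and 0.34. Glycolysis and hypoxia genes had 0.61, -0.10 and 0.02, with CA9, a carbonic anhydrase induced by low oxygen, at 2.63, 0.07 and 0.84, and hepatocyte metabolism genes had 0.52, -0.17 and -0.06. Proliferation genes had -0.32 in Hep3B against 0.02 and 0.05, both of which fell below 0 when the libraries were rescaled to the median ratio or the upper quartile. CENPF, a centromere protein with a long transcript, had -2.05, -0.69 and -0.59, and MKI67 -1.89, -0.39 and -0.45. Invasion genes had -0.56, 0.04 and 0.19, with ITGAV, an integrin subunit, at -2.31, 0.28 and 0.39. Epithelial genes were low in each line (-0.32, -0.30 and -0.21, percentiles 0.05, 0.03 and 0.08). Ribosomal proteins had 0.52, 0.39 and 0.46, above the central 95% of random lists in HCCLM3 and MHCC97H but not in Hep3B (percentiles 92.1, 100 and 100), with RPL26 at 0.50, 0.72 and 0.79. Nuclear encoded oxidative phosphorylation genes were at 0.53, 0.32 and 0.43 (percentiles above 99.9 in each), with COX7B of cytochrome oxidase at 0.49, 0.69 and 0.87. Of the remaining lists, medians in Hep3B, HCCLM3 and MHCC97H were 0.30, 0.21 and 0.04 for hepatocyte transcription factors, -0.07, 0.06 and -0.07 for oncofetal genes, -0.24, 0.11 and 0.41 for mesenchymal genes, 0.27, -0.06 and -0.01 for interferon genes, and -0.10, 0.30 and 0.29 for p53 targets. They were 0.48, 0.24 and 0.30 for translation factors, -0.04, -0.08 and 0.13 for aminoacyl-tRNA synthetases, 0.41, 0.35 and 0.33 for the integrated stress response, 0.22, 0.22 and 0.26 for endoplasmic reticulum folding, and 0.12, 0.25 and 0.33 for the proteasome. They were 0.02, 0.12 and 0.16 for the spliceosome, -0.34, 0.10 and 0.03 for iron response element genes, -0.38, 0.14 and 0.20 for C2H2 zinc fingers, and 0.33, 0.28 and 0.48 for histones. After either rescaling the medians of oncofetal genes and aminoacyl-tRNA synthetases in Hep3B were above 0. Those of oncofetal, invasion and iron response element genes in HCCLM3, and of hepatocyte transcription factors, glycolysis and iron response element genes in MHCC97H, were then below 0. So were mesenchymal genes in HCCLM3 with the upper quartile alone, and the spliceosome in HCCLM3 and aminoacyl-tRNA synthetases in MHCC97H with the median ratio alone. With no expression filter the interferon median in Hep3B became -0.10 and the zinc finger medians in HCCLM3 and MHCC97H -0.05 and -0.01, and with a filter at 5 RPKM the p53 target median in Hep3B became 0.01.

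**Figure D2:**
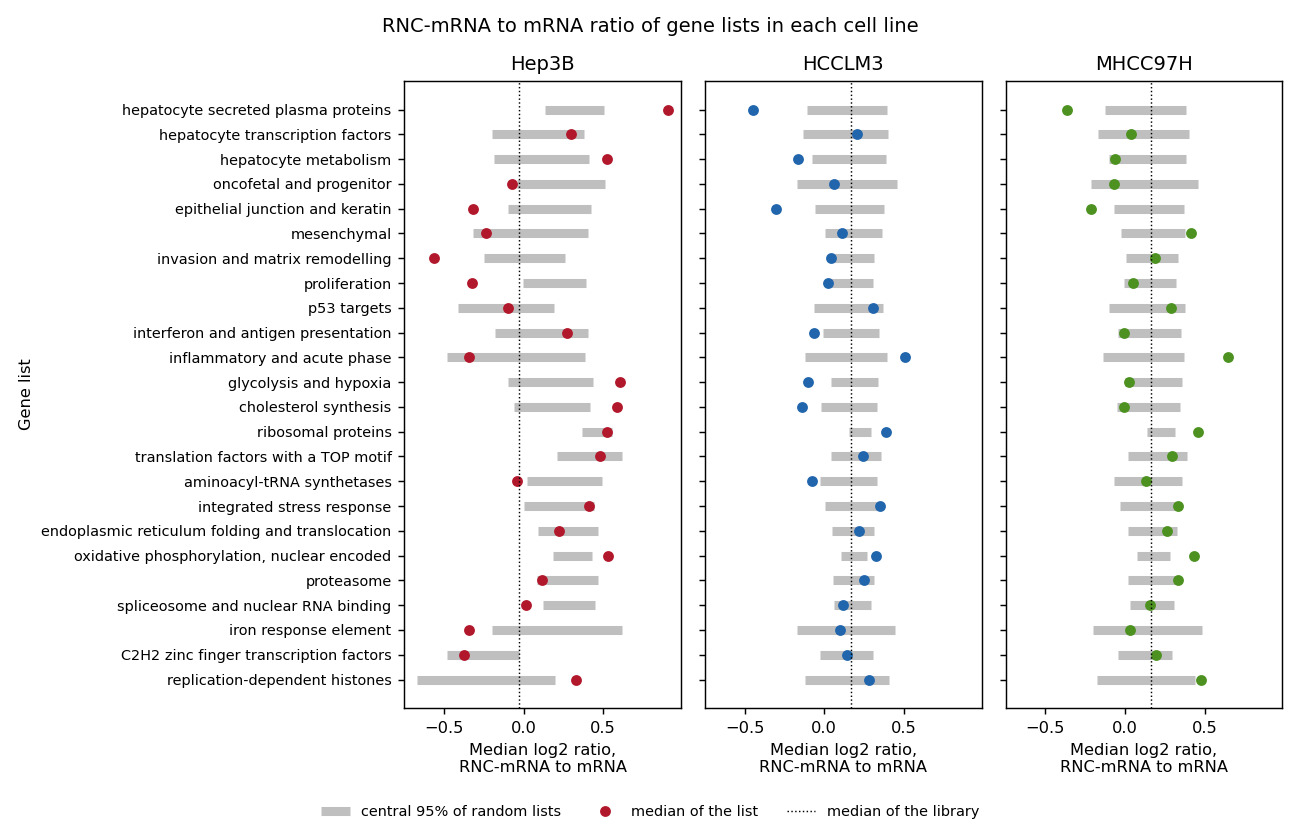
Median log2 ratio of RNC-mRNA to mRNA of 24 gene lists (one line of the vertical axis each) in Hep3B, HCCLM3 and MHCC97H, shown as coloured dots, with grey bars for the central 95% of 10000 random lists of matched expression and a dotted line for the library median. Hepatocyte secreted proteins lie at 0.91 in Hep3B and at -0.44 and -0.36 in the other lines.

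The ratio followed the length of the gene model, most of all in Hep3B. Across genes the Spearman correlation of log2 ratio and length was -0.556 in Hep3B, -0.046 in HCCLM3 and -0.105 in MHCC97H. Among genes with at least 10000 reads in both fractions it was -0.658, -0.284 and -0.304. With genes split by length into 5 groups of equal size, the median log2 ratio went from 0.41 in the shortest group to -0.52 in the longest in Hep3B, from 0.23 to 0.15 in HCCLM3 and from 0.24 to 0.11 in MHCC97H. Against this trend, secreted proteins had a median of 0.55 in Hep3B, -0.69 in HCCLM3 and -0.45 in MHCC97H. Against the library median these were 0.94, -0.61 and -0.52 before the trend was taken out. The percentile of oxidative phosphorylation genes in Hep3B became 66.8. Other Hep3B lists also moved into the central 95% of random lists. These included oncofetal genes (percentile 1.62 to 39.3), aminoacyl-tRNA synthetases (0.92 to 8.16), iron response element genes (0.62 to 2.615) and histones (99.5 to 69.5). Mesenchymal genes (5.5 to 0.36), inflammatory genes (7.58 to 0.66) and the proteasome (4.53 to 0.01) moved below it. Translation factors (64.4 to 99.15) and the integrated stress response (94.6 to 99.6) moved above it. FTL and FTH1, the ferritin genes whose translation is held back by iron regulatory proteins, had log2 ratios of -1.26, -1.70 and -1.85, and -0.92, -1.41 and -1.39. Neither passed edgeR's test over the 3 lines (adjusted p = 0.0589 and 0.0718). The iron response element list they belong to had medians of -0.34, 0.10 and 0.03. The share of the authors' read totals outside the gene table also differed by fraction, at 10.3% for mRNA and 5.98% for RNC-mRNA in Hep3B, 7.74% and 4.34% in HCCLM3, and 7.07% and 4.25% in MHCC97H. These ratios had no replicate check within a line, and whether they differ between lines was not tested.

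**Figure D3:**
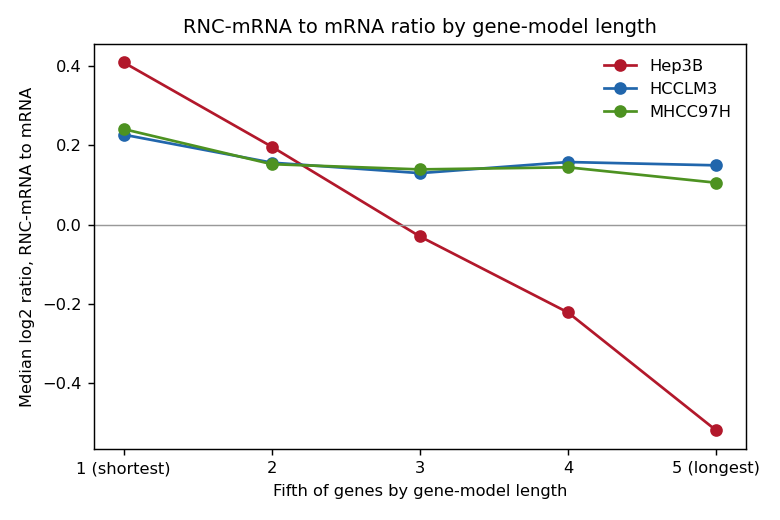
Median log2 ratio of RNC-mRNA to mRNA in 5 equal groups of the genes ordered by gene-model length, with 1 point per group and line for Hep3B (red), HCCLM3 (blue) and MHCC97H (green). The median goes from 0.41 to -0.52 in Hep3B and stays between 0.11 and 0.24 in the other lines.

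The last comparison asked which mRNAs departed from a ratio of 1 in the same direction in the 3 lines, with line as a block and n = 3 pairs of libraries. The test treats the 3 pairs as independent. HCCLM3 and MHCC97H are related and their ratios correlated at r = 0.946, so its p-values may be too small. Of 33 immediate early genes, which growth signals induce within minutes and which were listed after the values were seen, 6 rose in RNC-mRNA over mRNA and 27 did not pass. FOS had log2 ratios of 2.88, 2.80 and 2.93 in Hep3B, HCCLM3 and MHCC97H and an edgeR log2 ratio of 2.88 ± 0.14 (SE; adjusted p = 0.0389). DUSP1, a phosphatase of the MAP kinases, rose by 1.88 ± 0.20 (adjusted p = 0.0401 in edgeR), EGR1 by 1.77 ± 0.14 (adjusted p = 0.0389) and ZFP36, an mRNA decay factor, by 1.09 ± 0.14 (adjusted p = 0.0445), each on the log2 scale in 3 of 3 lines. Among the genes that fell, SPTAN1 and SPTBN1, which encode spectrin chains, had edgeR log2 ratios of -3.48 ± 0.18 and -2.37 ± 0.18, PLEC, the linker protein plectin, -2.32 ± 0.16, and LAMA5, a laminin chain, -1.80 ± 0.11, all with an adjusted p of 0.0389 and lower in 3 of 3 lines.

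By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8 of 11905 genes were higher and 316 lower in RNC-mRNA, 5 and 276 of them by at least 2-fold, with adjusted p of 0.0389 or more. The other 4 of the 8, named after their values were seen, were ATF3 at 1.10 ± 0.13 (edgeR adjusted p = 0.0417), RPL22L1 at 0.99 ± 0.12 (0.0423), CDKN2AIP at 0.88 ± 0.11 (0.0447) and DUSP6 at 0.76 ± 0.10 (0.0465). Others among the 10 lowest mean ratios passed too: PABPC1L at -2.57 ± 0.31, LENG8 at -2.47 ± 0.16, CHTF18 at -1.87 ± 0.21, PILRB at -1.85 ± 0.25 and 61E3.4 at -1.79 ± 0.22, with edgeR adjusted p from 0.0389 to 0.0467. FN1, at -2.18 ± 0.31, did not pass (adjusted p = 0.051 in edgeR). Of the 10 highest, JUN (1.08, adjusted p = 0.051), GADD45B (1.20, 0.0564), H1F0 (1.05, 0.117), GADD45A (0.98, 0.120), SLC51B (0.98, 0.202), NDRG1 (1.16, 0.223) and CA9 (1.12, 0.311) did not pass edgeR's test. NDRG1 and CA9 were high mainly in Hep3B. None of the 13 genes of the fixed panel passed, with ATF4 at 0.45 ± 0.15 (edgeR adjusted p = 0.145) and EEF1A1 at 0.29 ± 0.19 (0.371). The median gene-model length was 2174 bases for the 8 higher genes, 4072 for the 316 lower ones and 3272 for all genes tested.

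Among the gene lists few members passed by themselves, and none of the 24 lists passed in camera with an estimated correlation (adjusted p of 0.958 or more). Of 26 integrated stress response genes ATF3 rose and 25 did not pass, 7 rose when adjusted over the list alone, and the list median was 0.29. None of the 79 ribosomal protein genes passed, also when adjusted over the list alone, with a median of 0.43. Of 75 oxidative phosphorylation genes SDHA fell (-1.0 ± 0.11, edgeR adjusted p = 0.0404), against a list median of 0.39, and of 25 epithelial genes the desmosome gene DSP fell (-1.04 ± 0.12, edgeR adjusted p = 0.0404), with a median of -0.31 and, adjusted over the list alone, 1 member up and 2 down. In camera with a preset correlation, the lists that passed upward were ribosomal proteins (adjusted p = 1.38e-14), oxidative phosphorylation (3.24e-09), the integrated stress response (0.000997), translation factors with a TOP motif (0.011), the proteasome (0.0316) and endoplasmic reticulum folding (0.0458), and epithelial genes passed downward (0.011). None of these 7 passed in camera with an estimated correlation, where the adjusted p = 0.958 for each. That version rested on 2 residual degrees of freedom, with correlations of 0.753 for ribosomal proteins and 0.780 for oxidative phosphorylation. Failing there does not show that a list was unchanged. Of 36 invasion genes LAMA5 fell, and adjusted over the list alone 1 rose and 8 fell. SNRNP70 of the spliceosome list (-0.90 ± 0.12, edgeR adjusted p = 0.0452), CFI of the inflammatory list (-1.49 ± 0.12, 0.0389) and ZNF83 of the zinc finger list (-1.51 ± 0.16, 0.0401) were the other members that passed. Adjusted over the list alone, 2 spliceosome genes rose and 3 fell, 2 inflammatory genes, 4 zinc finger genes and 2 of 7 iron response element genes fell, 1 mesenchymal gene rose and 2 fell, 1 glycolysis gene rose and 1 oncofetal gene fell. No member of the 17 other lists tested passed over all genes.

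These calls rested on 2 residual degrees of freedom and on which lines were fitted: without Hep3B edgeR called 4187 genes higher and 4005 lower, without HCCLM3 3 and 119, without MHCC97H 9 and 284, and with no line block 0 and 0 (873 at an unadjusted p under 0.05), while DESeq2 called 662 and 1300 and dropping the expression filter gave 431 and 1443. ZFP36, ATF3, DUSP6, CDKN2AIP, RPL22L1, DSP, SDHA, SNRNP70, CFI and ZNF83 lost their call without HCCLM3, ATF3, DUSP6, CDKN2AIP, RPL22L1, DSP, SDHA and SNRNP70 also without MHCC97H, and LAMA5 and DSP with an offset for gene-model length. With the authors' totals DUSP1, PABPC1L, PILRB, 61E3.4, ZNF83, ATF3, DSP, SDHA, CDKN2AIP, DUSP6 and RPL22L1 lost theirs.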

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

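All tests in this part were chosen after the results were seen. Genes for secreted hepatocyte proteins stood out because their RNC-mRNA to mRNA ratio lay on opposite sides of 0 in different lines, with a median log2 ratio of 0.91 in Hep3B, -0.44 in HCCLM3 and -0.36 in MHCC97H. That difference between lines was not tested. Each line has 1 library per fraction, and the related lines HCCLM3 and MHCC97H were not treated as replicates of each other.

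For this pattern, gene-model length as the whole cause is argued against by a median of 0.55 in Hep3B after the length trend was taken out. Before that it was 0.94 against the library median. Low read counts are argued against by members with at least 1000 reads in both fractions. Their median against the library median was -0.43 or lower in HCCLM3 (9 genes) and MHCC97H (12 genes). A candidate explanation is that Hep3B, which expresses these genes strongly, loads their mRNAs well while the other lines do not. However, the gap of 1.35 in the list median sets 34 members in Hep3B against 14 in HCCLM3. No median over shared members was computed. The gap also goes with medium and serum as well as with line. These cannot be told apart, because each line was grown in 1 medium.

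The fall of the ratio with gene-model length was steepest in Hep3B. Low read counts as its cause are argued against by a rank correlation of -0.658 among Hep3B genes with at least 10000 reads in both fractions. Length may account for the high ratios of oxidative phosphorylation genes in Hep3B, whose percentile among random lists was 66.8 once the trend was taken out. For these genes and the ribosomal proteins in HCCLM3 and MHCC97H the lowest of the 4 percentiles was still 99.8 once the trend was taken out. This cannot decide on length as the whole cause there. The trend was taken over all genes, where the rank correlation with length was -0.046 and -0.105. Among genes with at least 10000 reads in both fractions it was -0.284 and -0.304, and the random lists were not matched on length. RNA breakage or a loss of long complexes during preparation cannot be told apart from a difference in translation for the gap of -0.93 between the longest and shortest genes in Hep3B, as no values along the transcripts were analysed here.

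Immediate early genes, listed because some of them had the highest ratios, had list medians of 0.51, 0.68 and 0.83 in Hep3B, HCCLM3 and MHCC97H, so no test of the list itself is given. With the length offset the edgeR list median was 0.57, against 0.62 without it, so the offset took out little of it. Among members with at least 1000 reads in both fractions the median lay at least 0.46 above the library median in each line. As the list was picked from these same ratios, neither value is a test of length or low read counts as the cause. Induction while cells were handled for the RNC-mRNA preparation may also raise these transcripts. With a list median of 0.62 and no library of handled cells analysed here, it cannot be told apart from their translation.

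For the 324 genes past edgeR's threshold over the 3 lines, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The highest count in another split was 1. Of these splits 4 part the 2 libraries of every line as the model does, and the 3 others of them called 0. In those 3 a line is exchanged against the others, so a ratio shared by the lines adds to the residual spread. Few calls could arise there, and their absence decides nothing about the 324 genes.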

How the results depend on the processing

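The authors' totals, the length offset and the 3 added lists were chosen after the data were seen, and the other alternatives were planned. Of 214 counts and correlations under alternatives, 126 stayed within 1.5 times the main value or within their error and 88 moved. Of 1157 list medians 1078 stayed within their spread, 72 moved by more, and 7 that lay outside the central 95% of random lists changed sign. Counting medians inside that range too, 17 changed sign on rescaling to the median ratio, 16 with the upper quartile, 13 with no filter, 5 with a filter at 5 RPKM and 0 with either pseudocount. Among those with a filter changed, the iron response element median for MHCC97H over Hep3B mRNA became -0.33 with no filter, the stellate marker median for MHCC97H over Hep3B RNC-mRNA 0.04, and the leukocyte marker median for HCCLM3 over Hep3B mRNA 0.70 with a filter at 5 RPKM. Of 24403 values for single genes 18913 stayed, 5018 moved, 420 gained a call and 52 lost one. The pseudocount alternatives do not apply to the test on counts and were not run for it.

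Line counts depend on the pseudocount, as low genes need a larger gap to reach a ratio of 4. With a pseudocount of 1, in mRNA 662 genes were higher and 742 lower in HCCLM3 than in Hep3B, 661 and 699 in MHCC97H than in Hep3B, and 9 and 8 in HCCLM3 than in MHCC97H. In RNC-mRNA these were 794 and 776, 800 and 733, and 11 and 11. In both fractions 537 genes stood above and 510 below in Hep3B, 6 and 1 in HCCLM3, and 5 and 2 in MHCC97H. Ratios of at most 0.5 numbered 509 in Hep3B, 167 in HCCLM3 and 193 in MHCC97H, and ratios of at least 2 numbered 38 in HCCLM3 and 26 in MHCC97H. With a pseudocount of 0.01, 12 genes stood below both other lines in HCCLM3.

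With a filter at 5 RPKM fewer genes were compared. In mRNA 712 genes were higher and 780 lower in HCCLM3 than in Hep3B, 675 and 721 in MHCC97H than in Hep3B, and 11 and 11 in HCCLM3 than in MHCC97H. In RNC-mRNA these were 851 and 761, 858 and 739, and 13 and 14. In both fractions 546 genes stood above and 517 below in Hep3B, 6 and 2 in HCCLM3, and 7 and 3 in MHCC97H. Ratios of at most 0.5 numbered 223 in Hep3B, 100 in HCCLM3 and 108 in MHCC97H, and ratios of at least 2 numbered 34 in HCCLM3 and 21 in MHCC97H. With no filter, 16 genes stood below both other lines in HCCLM3, ratios of at most 0.5 numbered 2380, 1244 and 1243 in Hep3B, HCCLM3 and MHCC97H, and the correlation of mRNA and RNC-mRNA differences between HCCLM3 and MHCC97H was 0.832. Among genes at 1 RPKM in all 6 libraries, which leaves out genes absent from a line, the mRNA counts were 348 and 347 for HCCLM3 over Hep3B, 323 and 284 for MHCC97H over Hep3B, and 2 and 3 for HCCLM3 over MHCC97H. In RNC-mRNA they were 478 and 346, 474 and 326, and 4 and 3, and 135 genes had a ratio of at least 2 in Hep3B. At 1 RPKM, 11742, 10942, 11467, 11152, 11489 and 11186 genes were detected in Hep3B mRNA, Hep3B RNC-mRNA, HCCLM3 mRNA, HCCLM3 RNC-mRNA, MHCC97H mRNA and MHCC97H RNC-mRNA, of 18016, 17527, 17830, 17607, 17910 and 17667 with any read.

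Rescaling to the median ratio moved the median of all genes at 1 RPKM in the 6 libraries from -0.02, 0.18 and 0.16 to 0.08, 0.03 and 0.02 for the ratio in Hep3B, HCCLM3 and MHCC97H. It left 34 genes with a ratio of at least 2 in HCCLM3 and 23 in MHCC97H, and rescaling to the upper quartile left 43 and 30. Among list medians outside the central 95% of random lists, 4 changed sign under rescaling to the median ratio: oncofetal genes (0.0309) and aminoacyl-tRNA synthetases (0.0567) for the ratio in Hep3B, proliferation (-0.126) for the ratio in HCCLM3, and ribosomal proteins (-0.0065) in MHCC97H over Hep3B mRNA. Under the upper quartile, oncofetal genes (0.0117), aminoacyl-tRNA synthetases (0.042) and proliferation (-0.0962) did so in the same ratios. The others that changed sign lay inside that range.

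The test over the 3 lines changed most. Against 8 genes higher and 316 lower, edgeR called 431 and 1443 with no filter, 0 and 0 with no line block (873 at an unadjusted p under 0.05), 5 and 188 with the authors' totals, and 44 and 367 with the length offset. DESeq2 called 662 and 1300, which include all 8 and 314 of the 316. Leaving out a line gave 3 to 4187 higher and 119 to 4005 lower, the upper ends without Hep3B and the lower ends without HCCLM3. Without HCCLM3 3 of the 8 and 94 of the 316 were called, and without MHCC97H 4 and 174. The counts stayed within 1.5 times with a filter at 5 RPKM (10 and 219), RLE scaling (8 and 298) and upper quartile scaling (11 and 415). The causes of the other changes were not tested. The fit without Hep3B held only the 2 related lines, whose ratios correlated at r = 0.946, against 0.352 and 0.387 with Hep3B. Among genes named, FN1 passed with no filter, with a filter at 5 RPKM, with upper quartile scaling, with the authors' totals and without Hep3B. PABPC1L, PILRB, 61E3.4, DUSP1, ZNF83, ATF3, DSP, SDHA, CDKN2AIP, DUSP6 and RPL22L1 did not pass with the authors' totals. Depth limits low genes most, since counting alone gives a log2 half-width of 0.40 at 100 reads and 0.13 at 1000.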

Other observations

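The lists and genes in this part were chosen after their values were seen, and no explanation was tested for them. Targets of NRF2, the transcription factor of the oxidative stress response, were higher in HCCLM3 and MHCC97H than in Hep3B by the size rule, 21 and 22 of 30 in mRNA with 0 lower, and a median log2 ratio of 3.0 in both. NQO1, a quinone reductase, stood at 3.75 RPKM in Hep3B mRNA, 322.5 in HCCLM3 and 324 in MHCC97H, AKR1B10, an aldo-keto reductase, at 2.56, 1319 and 2037, TXNRD1 at 25.8, 521 and 548, and GCLM, which makes glutathione, at 2.17, 45.6 and 48.6. AKR1C1 stood at 0.149, 255 and 290, with reads that near-identical paralogs make uncertain. KEAP1, the inhibitor of NRF2, stood at 48.9, 8.44 and 7.71 RPKM, and NFE2L2, which encodes NRF2, at 51.5, 22.4 and 21.1. In RNC-mRNA the list medians were 2.87 and 3.01.

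Some cancer-testis gene families, silent in most adult tissues, set HCCLM3 and MHCC97H apart. Summed over each family, with the handling of reads shared between copies not given in the sources used here, SSX stood at 2.36 RPKM in Hep3B mRNA, 109 in HCCLM3 and 11.9 in MHCC97H, and SPANX at 0.146, 580 and 100.3. GAGE stood at 0.188, 1.47 and 18.1 RPKM, while MAGEA stood at 4.97, 32.8 and 40.2.

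Genes that set Hep3B apart lay next to each other more often than random sets of the same size, by the order of 12515 genes in the RefSeq annotation on GRCh38.p14. Of the 897 genes above both other lines, 876 were placed and made 140 adjacent pairs (1000 random sets: median 63, central 95% 50 to 77), of which 105 joined genes with unlike names (random median 57). Of the 834 below, 806 were placed and made 133 (median 52, 39 to 65), of which 84 had unlike names (random median 49). Runs included 8 genes from PPP4R4 through the SERPINA cluster, APOE with its APOC neighbours with 4, and MDFIC, TES, CAV2, CAV1 and MET with 5.

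Hypoxia-inducible genes had RNC-mRNA to mRNA medians of 0.71 in Hep3B, 0.01 in HCCLM3 and 0.17 in MHCC97H, and over the 3 lines camera gave p = 0.0664, and p = 0.534 with an estimated correlation. For NRF2 targets the medians were 0.06, 0.25 and 0.21, and camera gave p = 0.128, and p = 0.509 with an estimated correlation. As both lists were written after these values were seen, the p-values only describe them and are no test.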
